A study of Homo sapiens with 12 samples.

How the data were processed

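Expression was measured with one-colour Agilent arrays in 12 samples of the human embryonic stem cell line Shef-1 grown on Matrigel, in 4 groups of 3 replicates: PI3Kα-depleted, PI3Kβ-depleted, N/C-MYC-silenced and siRNA control. Total RNA was column-purified and labelled with Cy3, per the labels' protocols. The spot intensity values were made by the authors with Feature Extraction 10.7.3.1, which subtracted a background estimated by spatial detrending, applied multiplicative detrending and replaced low spots with a surrogate value, per the file headers. The headers give probe positions on hg19, and no exon or UTR annotation of that build was used here. The authors also deposited a table of log2 values of the same arrays, whose method is not given in the sources used here. From the values, its ranks followed the median spot signal minus the median local background exactly (Spearman's rho 1 on every array, across spots), and its column medians lay between 8.23508 and 8.23852, so that it was read as quantile-normalised and used only as an alternative. The direction of that table follows the intensities, and its exact background step stays unknown. Each array held 44495 spots, of which 43118 were not controls, and no spot was saturated. Arrays give no counts, so their number limits the precision.

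Control spots and spots marked as outliers (316 to 602 per array) were left out. The processed signal was put on the log2 scale and each array's 75th percentile subtracted. Spots of one probe were averaged, which concerned 999 probes spotted 10 times each, among 34127 probes. Probes were named by accession through a gene table of assembly GRCh38.p14, used for names only. This named 25771 probes, current or older symbols named 2207 and 499, and 1354 kept the name in the file, while 4296 stayed unnamed. The result was 29831 named probes of 21745 genes. A probe was kept if it was well above background on all arrays of at least 1 group, and each gene was represented by its kept probe with the highest mean, measured on at least 2 arrays of each group, which left 15413 genes. Y-linked genes and XIST are not reported here. Probes of opposite sign within a gene occurred for 4 of 20 genes called with several probes in the comparison of PI3Kβ with PI3Kα depletion, 33 of 179 in that of N/C-MYC silencing with PI3Kβ depletion and 0 of 34 in that of N/C-MYC silencing with control. The other AXIN2 probe differed from control by 0.81, −0.38 and 2.33 in PI3Kα-depleted, PI3Kβ-depleted and N/C-MYC-silenced cells.

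Group means were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in a fit of all 12 arrays with 8 residual degrees of freedom, and genes were called at a Benjamini-Hochberg adjusted p below 0.05. The same fit with the slide as a block has 6. Replicate numbers were checked for pairing through the deviations of arrays from their group means over 14527 genes measured on every array. Arrays with the same number, which lay on one slide, correlated by 0.158 to 0.629 in all 18 pairs, above the bound of 0.1, and all 12 arrays were closest to arrays of their own number, so that the numbers pair the samples. Blocked values are therefore given beside a result where they change a call or move a count by over 1.5 times. "Rose" and "fell" refer to differences that passed in the fit named. Where a probe was not well above background on any array of a group, the fold is given as "at least". It sets the mean of the brighter group against, per array of the dimmer group, the higher of its own signal and the lowest signal among probes well above background. Where only some arrays of a group were well above background, their number is given. The series text calls the replicates biological and gives no further detail. The p-values therefore measure the spread between these samples, which may be technical in part.

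Gene lists were tested with camera in limma with a preset correlation of 0.01, and again with an estimated correlation, over the 14527 complete genes, with adjustment over the lists within a comparison. Medians and counts cover all measured members. Lists share members (without streak genes, 15 definitive endoderm and 17 mesoderm genes remain), so their shifts are not independent of each other. The 35 lists (1044 entries, 1041 with a probe) cover lineage and cell type markers, PI3K, MYC, WNT, TGF-β, Polycomb, cell cycle, ribosome, metabolic, stress, interferon, p53, histone and reference genes. They, the groups, the comparisons, the main design, most alternatives and the rule for named genes were chosen before the data were examined. The rule takes the genes of the silenced and pluripotency, streak, Polycomb and WNT set in every comparison, up to 10 called genes per direction with the same sign on all slides, up to 4 called members per list, 5 genes per direction where none is called, and 2 members of a list with no call. It was applied again to the calls of the blocked fit after the data had been seen. The streak genes plotted, the genes shared between comparisons and those of the combined test in the closing observations were also chosen after their values were seen.

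The gene tests were tested on simulated data made from 14527 genes, with 100 genes changed by a log2 of 1 and 100 by 2. At a log2 of 2, the fit without the block recovered 55, 64, 56, 58 and 68 of 100 in the comparisons of PI3Kα, PI3Kβ and N/C-MYC with control, PI3Kβ with PI3Kα and N/C-MYC with PI3Kβ, and the blocked fit 92, 97, 90, 97 and 95. At a log2 of 1 these numbers were 0, 0, 0, 2 and 1, and 17, 16, 23, 16 and 15. False calls numbered 0 to 1 without and 6 to 12 with the block. The simulated data held an added shift per slide and the spread of the blocked fit, equal on every array. As the blocked fit assumes just this, the numbers may favour it, and a wider spread on a dim array was not simulated. Of 100 unchanged lists 3, 0, 1, 4 and 2 had an unadjusted p below 0.05 in camera. These lists were drawn at random from genes simulated to vary independently. They therefore cannot show how often camera calls unchanged lists whose genes vary together. Alternatives were quantile normalization, normexp background correction with an offset of 50, centring on the median, the authors' table, other filters on dim probes, the mean of a gene's probes, the slide block, only the groups compared, array weights, a minimum log2 change of 1 and leaving out each array. Alternatives without slide 1, without the dim array, and those combined with the slide block were added after seeing the data. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots.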

Results

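Gene expression was profiled in Shef-1, an established human embryonic stem cell line. By the labels, the cells had PI3Kα, PI3Kβ or both N-MYC and C-MYC silenced, or were given a control siRNA. The series text speaks of 3 cell lines, and only the sample titles of the control name the cells as WT. The sources used here do not say whether the depleted groups were stable lines or cells silenced transiently. A difference from the siRNA control can therefore hold a difference between lines as well. PI3Kα and PI3Kβ are the lipid kinases whose catalytic subunits are encoded by PIK3CA and PIK3CB, and N-MYC and C-MYC are the transcription factors encoded by MYCN and MYC. Total RNA from 12 samples, 3 per group, was labelled with Cy3 and hybridised to one-colour Agilent arrays. The labels name the stem cell medium mTeSR1 and a NODAL-free medium, without saying in which of them each sample was grown. Values of NODAL, its antagonists and its targets are therefore open to a difference in medium between samples. The 75th percentile of the processed signal was 683 on the N/C-MYC-silenced replicate 1 array and lay between 1176 and 2849 on the other arrays. Between 58.1% and 72.4% of spots were well above background. Pearson correlations between arrays of a group, across genes that are not independent replicates, were 0.964 to 0.981 for the control, 0.95 to 0.967 for PI3Kα, 0.955 to 0.972 for PI3Kβ and 0.935 to 0.981 for N/C-MYC. Each replicate number was a slide of its own with all 4 groups on it. A group lay at the same position on every slide, so that group and position cannot be told apart. All levels below are log2 signals relative to the 75th percentile of the array, given as mean ± SD over n = 3 arrays, and adjusted p-values are from limma over 15413 genes, without a block unless the slide block is named. The series text calls the replicates biological and gives no further detail, so the p-values measure the spread between these arrays.

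Each silenced gene had a lower mean in its own group than in the control, on all 3 slides. PIK3CA (probe A_23_P92057; chromosome 3, 178948163 to 178951939, hg19) stood at −1.64 ± 0.16 in control, −3.48 ± 0.60 in PI3Kα-depleted, −1.21 ± 0.20 in PI3Kβ-depleted and −1.74 ± 0.09 in N/C-MYC-silenced cells. Its 3.58-fold lower mean under PI3Kα depletion did not pass against the control (adjusted p = 0.222, and 0.0835 with the slide block), whereas its difference from the PI3Kβ-depleted cells passed in both fits (adjusted p = 0.0239 and 0.00957). PIK3CB (probe A_23_P346969; chromosome 3, 138374281 to 138374340) stood at −2.36 ± 0.98 in control, −2.25 ± 0.54 in PI3Kα-depleted, −5.45 ± 0.71 in PI3Kβ-depleted and −2.74 ± 0.99 in N/C-MYC-silenced cells. It was 8.50-fold lower in PI3Kβ-depleted than in control cells, a difference that passed with the slide block (adjusted p = 0.00147) and not without it (adjusted p = 0.665), and its probe was well above background on 2 of the 3 PI3Kβ-depleted arrays. MYCN (probe A_24_P94402; chromosome 2, 16086767 to 16086826) was at 3.21 ± 0.30 in control, 2.04 ± 0.88 in PI3Kα-depleted, 3.11 ± 0.40 in PI3Kβ-depleted and 1.66 ± 0.54 in N/C-MYC-silenced cells, a 2.92-fold lower level in the last group that passed only with the slide block (adjusted p = 0.026 against 0.27). The MYC gene (probe A_23_P215956; chromosome 8, 128753268 to 128753327) was at 2.57 ± 0.87, 2.40 ± 0.54, 2.23 ± 1.13 and 1.68 ± 0.20 in the same order of groups. Its 1.87-fold lower mean in N/C-MYC-silenced cells passed in neither fit (adjusted p = 0.56 and 0.157). MYCN was also 2.24-fold lower in PI3Kα-depleted than in control cells, a difference that passed in neither fit (adjusted p = 0.898 and 0.215). In the 6 fits that left out 1 array, the blocked call of PIK3CB was kept in 6 and that of MYCN in 1 (adjusted p up to 0.149), and the difference of PIK3CA between the PI3K groups in 5 with and 1 without the block. The plot of the silenced genes shows these levels array by array.

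**Figure D1:**
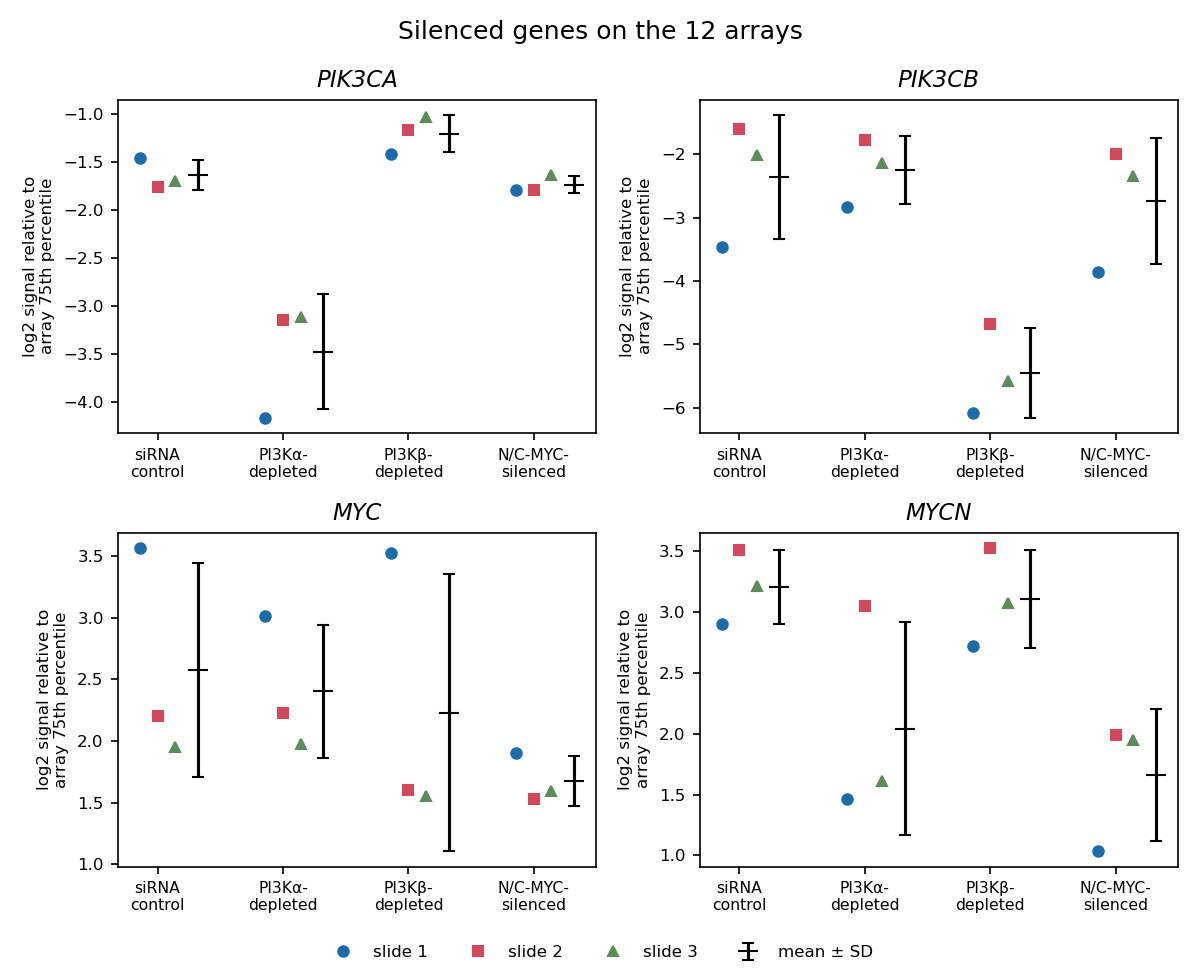
Level of PIK3CA, PIK3CB, MYC and MYCN on each of the 12 arrays (y axis, log2 signal relative to the array's 75th percentile; x axis, group), with a marker per slide and the mean ± SD of the 3 arrays in black. PIK3CB averages −5.45 in PI3Kβ-depleted cells and −2.74 to −2.25 in the other groups.

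The comparison of PI3Kα-depleted with control cells asked which transcripts differ when the α isoform is silenced. Besides PIK3CA, the genes farthest from zero relative to their error were MXD1, which encodes a MAX partner that opposes MYC (3.01-fold higher), the trefoil peptide gene TFF3 (3.80-fold higher), SELENOP (2.71-fold higher), TMEM123 (2.72-fold lower), the actin regulator gene CYFIP2 (2.47-fold lower) and CDC42EP3 (at least 2.24-fold lower, with no PI3Kα-depleted array well above background). None of these passed (adjusted p = 0.222 for each). LEFTY2, a secreted antagonist of NODAL, was 4.99-fold higher and had an adjusted p of 0.0753 with the slide block. The pluripotency factors POU5F1, SOX2 and NANOG differed from control by 0.55, 0.50 and −0.31 on the log2 scale, the primitive streak factors TBXT, EOMES and MIXL1 by 0.73, 0.12 and 0.94, and the chromatin and WNT genes EZH2, CTNNB1 and AXIN2 by −0.70, −0.17 and −0.37. None of them passed, and the other AXIN2 probe had the opposite sign (0.81). Of the 24 measured p53 targets 20 lay lower (median −0.31, adjusted p = 0.0176, and adjusted p = 0.848 with an estimated correlation), including SESN1 at −0.86 and FAS at −0.69. Of 19 definitive endoderm genes 14 lay higher (median 0.45, adjusted p = 0.0381, and adjusted p = 0.675 with an estimated correlation), including HHEX at 1.68. No member of either list passed, over all genes or adjusted over the list alone. No gene passed between PI3Kα-depleted and control cells with limma, with or without the slide block, while 841 genes without and 1639 with the block had an unadjusted p below 0.05. The 841 were 5.46% of the genes tested, close to the share that chance alone would give, whereas the 1639 with the block lay above it. The fit without the block leaves differences between slides in its error. The blocked count became 2 after quantile normalization, 1 in the authors' value table, 5 over probes well above background on all 12 arrays and 4 with array weights. The stress response targets of ATF4 shifted lower only with the slide block (18 of 25 lower, adjusted p = 0.0418 against 0.0513 without it, and adjusted p = 0.698 with an estimated correlation). The p53 shift was lost without PI3Kα-depleted replicate 2 (adjusted p = 0.372) or 3 (0.124) or control replicate 1 (0.0593), and the endoderm shift without PI3Kα-depleted replicate 2 (0.154) or 3 (0.124) or control replicate 2 (0.0694) or 3 (0.228).

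The comparison of PI3Kβ-depleted with control cells addressed the isoform named in the title of the series together with primitive streak gene expression. GSC, a homeobox gene of the organiser and anterior primitive streak (chromosome 14, 95234740 to 95234799), stood at −1.63 ± 0.48 in control and −3.67 ± 0.55 in PI3Kβ-depleted cells. With the slide block GSC fell by 2.03 on the log2 scale, or 4.09-fold (SE 0.252, adjusted p = 0.03). The same fit had PIK3CB lower, and CGA, which encodes the common α subunit of the glycoprotein hormones, higher by at least 5.54-fold (adjusted p = 0.00312), as no control array had its probe well above background. LOC100131820 was higher by at least 1.48-fold (adjusted p = 0.038). Further primitive streak and mesendoderm genes lay lower on all 3 slides without passing: MIXL1 at −2.80 (SE 0.649), TBXT at −2.07 (SE 0.647), EOMES at −1.50 (SE 0.308) and CER1 at −1.81 (SE 0.896), with adjusted p-values of 0.163 to 0.284 with the slide block. MIXL1, TBXT and CER1 were well above background on 2 of the 3 PI3Kβ-depleted arrays, and CER1 on 2 of the 3 control arrays. Without the slide block no gene passed between PI3Kβ-depleted and control cells in limma (631 at an unadjusted p below 0.05, smallest adjusted p 0.461), and with it 4 did (2 higher, 2 lower, and 1253 at an unadjusted p below 0.05). The 631 were 4.09% of the genes tested, below the share that chance alone would give, whereas the 1253 with the block lay above it. PIK3CB kept its blocked call in all 6 fits that left out 1 array and CGA in 5 (adjusted p = 0.0527 without PI3Kβ-depleted replicate 3). GSC and LOC100131820 kept theirs in 0 (adjusted p up to 0.305). The blocked count became 2 without PI3Kβ-depleted replicate 1 or any one control array, 5 without PI3Kβ-depleted replicate 2 and 1 without PI3Kβ-depleted replicate 3. None of the 4 passed in limma with normexp background correction (634 genes at an unadjusted p below 0.05), in the authors' value table (774) or from the compared groups only (1929), and no other gene did. The count became 1 after quantile normalization or over probes well above background on all 12 arrays, 2 without a filter on dim probes and 18 with array weights. The plot of primitive streak genes gives their levels on each array.

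**Figure D2:**
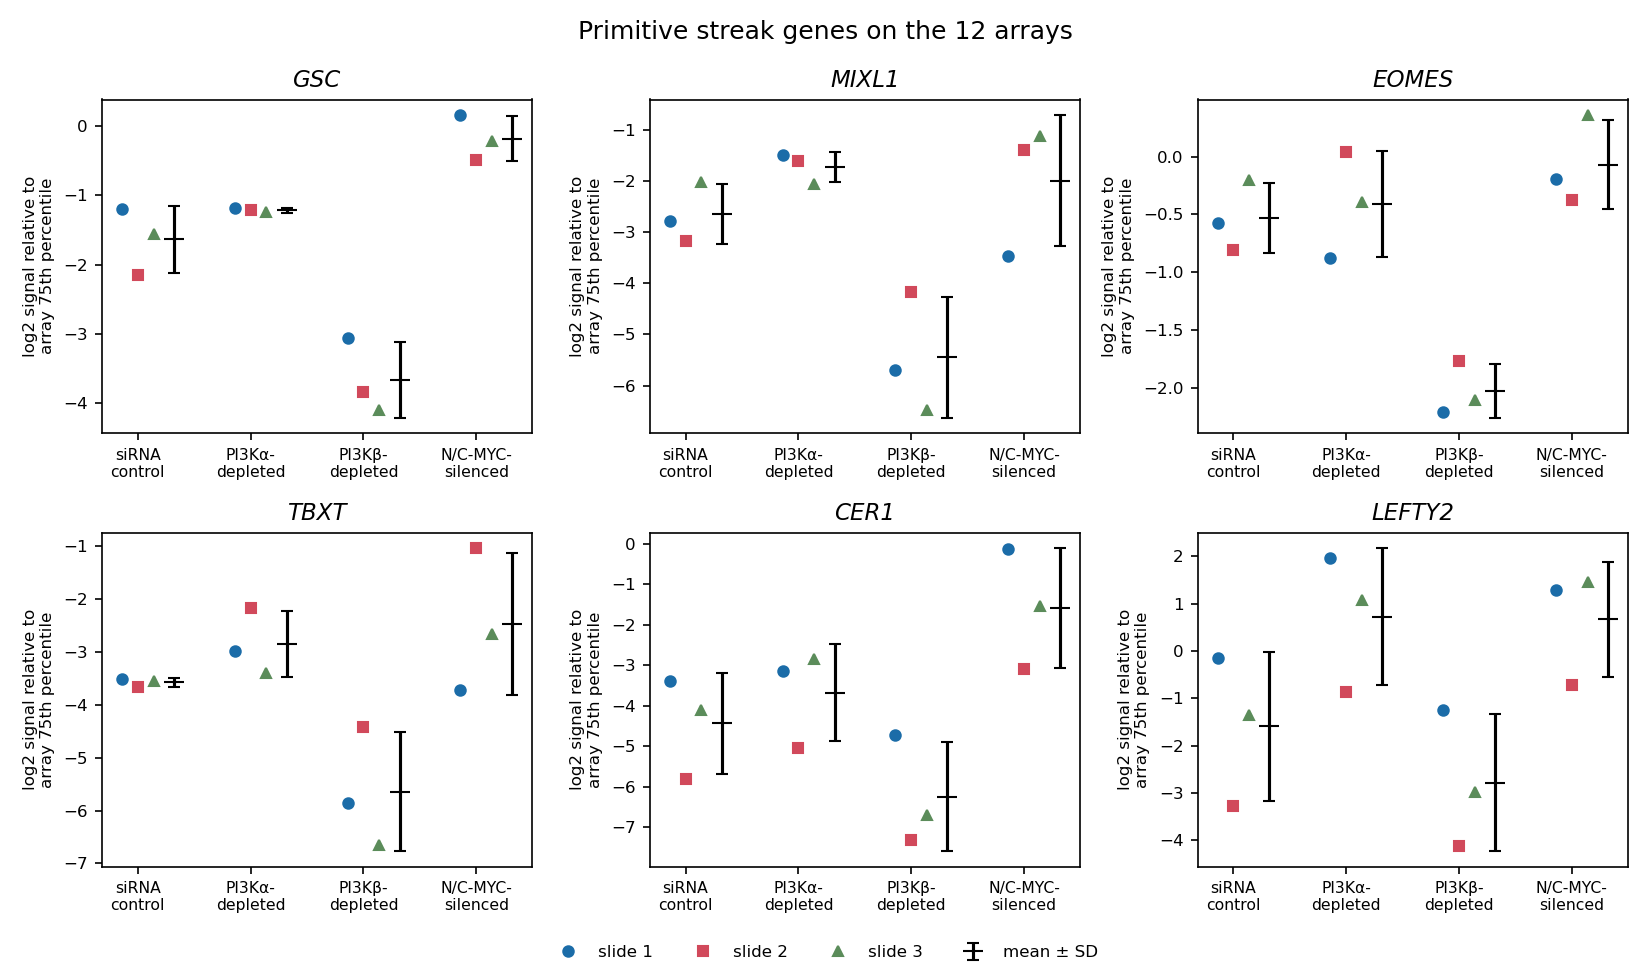
Level of 6 primitive streak and mesendoderm genes on each of the 12 arrays (y axis, log2 signal relative to the array's 75th percentile; x axis, group), with a marker per slide and the mean ± SD of the 3 arrays in black. GSC averages −3.67 in PI3Kβ-depleted cells, −1.63 in control, −1.21 in PI3Kα-depleted and −0.18 in N/C-MYC-silenced cells.

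As a group, 23 of the 28 measured primitive streak and mesendoderm genes lay lower in PI3Kβ-depleted than in control cells, with a median of −0.53 and slide medians of −0.57, −0.35 and −0.73 (adjusted p = 8.77e-09, and adjusted p = 0.265 with an estimated correlation). Adjusted over the list alone, 8 members fell without the block and 11 with it, against 0 and 1 over all genes. Of 29 transcriptional targets of WNT and β-catenin 18 lay lower (median −0.26, adjusted p = 0.00239, and adjusted p = 0.489 with an estimated correlation), and 5 fell adjusted over the list alone. SP5 at −2.07 and the feedback inhibitor gene NKD1 at −1.30 had the smallest p-values of this list, while AXIN2 stood at −0.15 (−0.38 for its other probe) and CTNNB1, which encodes β-catenin, at 0.01. Of 25 TGF-β and NODAL targets 14 lay lower (median −0.10, adjusted p = 0.0486, and adjusted p = 0.49 with an estimated correlation), with NODAL at −1.78 and LEFTY1, also a streak gene, at −1.47. Of 14 replication-dependent histone genes 13 lay lower (median −0.43, adjusted p = 0.00239, and adjusted p = 0.49 with an estimated correlation), and of 25 cholesterol synthesis genes 18 (median −0.20, adjusted p = 0.0486, and adjusted p = 0.817 with an estimated correlation). The p53 targets lay higher in 20 of 24 cases (median 0.32, adjusted p = 0.00646, and adjusted p = 0.678 with an estimated correlation), with TP53INP1 at 0.86 and TRIAP1 at 1.10. POU5F1, SOX2, NANOG and EZH2 differed from control by −0.03, 0.60, −0.35 and −0.45 and did not pass. The streak and histone shifts held without any one array. The WNT target shift was lost without PI3Kβ-depleted replicate 3 (adjusted p = 0.154) or control replicate 1 (0.052), the p53 shift without PI3Kβ-depleted replicate 1 (0.203). The cholesterol shift was lost without PI3Kβ-depleted replicate 1 (0.579) or 3 (0.0655) or control replicate 2 (0.662), and the TGF-β and NODAL shift without PI3Kβ-depleted replicate 3 (0.583) or control replicate 1 (0.224). Their medians turned positive without control replicate 2 (0.05) and PI3Kβ-depleted replicate 3 (0.03) respectively.

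The comparison of N/C-MYC-silenced with control cells asked which transcripts differ in cells labelled as silenced for both MYC factors. Of the 2 targets, MYCN was lower with the slide block only, and the lower mean of MYC passed in neither fit. Ribosome biogenesis genes known as MYC targets lay lower in 49 of 59 cases (median −0.36, adjusted p = 4.53e-08, and adjusted p = 0.106 with an estimated correlation), led by the arginine methyltransferase gene PRMT3 at −1.33 and the nucleolar factor gene NOLC1 at −0.95, which did not pass singly. S phase genes lay lower in 27 of 30 cases (median −0.27, adjusted p = 3.29e-05, and adjusted p = 0.0848 with an estimated correlation). CCNE2, which encodes cyclin E2, fell 2.76-fold with the slide block (adjusted p = 0.0378, against 0.135 without it). G2/M phase genes lay lower in 24 of 31 cases (median −0.36, adjusted p = 0.00142, and adjusted p = 0.43 with an estimated correlation), and cholesterol synthesis genes in 20 of 25 (median −0.11, adjusted p = 0.0156, and adjusted p = 0.592 with an estimated correlation). Several lists of markers of differentiated or other cell states shifted higher. They comprised definitive endoderm (18 of 19, median 0.60, adjusted p = 0.00266), naive pluripotency (12 of 13, median 0.57, adjusted p = 0.00266) and endothelial and blood genes (11 of 12, median 0.71, adjusted p = 0.00357), each with adjusted p = 0.0848 with an estimated correlation. They also comprised primitive streak genes (25 of 28, median 0.46, adjusted p = 0.00993), interferon response genes (15 of 19, median 0.48, adjusted p = 0.00993), EMT and adhesion genes (21 of 28, median 0.47, adjusted p = 0.023) and neuroectoderm genes (17 of 20, median 0.46, adjusted p = 0.0282), each with adjusted p = 0.43 with an estimated correlation. Polycomb-bound developmental regulators did so in 44 of 51 cases (median 0.44, adjusted p = 0.0169, and adjusted p = 0.771 with an estimated correlation). Neurons and glia genes did not, with 8 of 10 lower (slide medians −0.182, −0.283 and −0.305, adjusted p = 0.239), nor did neural crest genes, with 7 of 13 lower (slide medians −0.457, 0.058 and 0.148, adjusted p = 0.749). No member of these 12 lists passed over all genes without the block. Adjusted over the list alone, 3 interferon genes and 1 each of the naive, streak, Polycomb-bound and EMT genes lay higher and 1 S phase gene lower. Without N/C-MYC-silenced replicate 1 the shifts of the G2/M (adjusted p = 0.0892), primitive streak (0.155), EMT (0.185), neuroectoderm (0.245), Polycomb-bound (0.545) and cholesterol synthesis genes (0.245) were lost, and those of the ribosome biogenesis, S phase, endoderm, naive and endothelial lists held without any one array. Control replicate 2 was also needed for the streak (0.122), neuroectoderm (0.0592), Polycomb-bound (0.113) and cholesterol (0.211) shifts. Control replicate 3 was needed for the EMT (0.101), neuroectoderm (0.17) and Polycomb-bound (0.169) shifts, and control replicate 1 (0.08) and N/C-MYC-silenced replicate 2 (0.0577) for the interferon shift. Mesoderm and fibroblast markers shifted higher only with the slide block (15 of 19 and 12 of 15 higher, adjusted p = 0.00464 and 0.00852, and adjusted p = 0.302 and 0.171 with an estimated correlation). When all genes were put in 4 groups by brightness, the dimmest lay higher on slides 1, 2 and 3 (0.422, 0.22 and 0.223 on the log2 scale). The other groups stood at −0.066 to 0.108. The lists were not set against genes of similar brightness in any comparison. A shift of dim genes as a whole therefore stays open for the lists that lay higher.

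With the slide block 195 genes passed between N/C-MYC-silenced and control cells, 162 higher and 33 lower (2988 at an unadjusted p below 0.05). Among those that rose were the cyclin-dependent kinase inhibitor gene CDKN2B (6.80-fold, SE 0.312, adjusted p = 0.00898), CPLX3 (7.0-fold, SE 0.273 on the log2 scale, adjusted p = 0.00277), the smooth muscle actin gene ACTG2 (6.95-fold, adjusted p = 0.0221), the calcium-binding protein gene S100A6 (6.62-fold, adjusted p = 0.0124) and the fatty acid receptor gene CD36 (6.21-fold, adjusted p = 0.0124). CER1 and LEFTY2, both secreted NODAL antagonists, rose 7.19-fold (adjusted p = 0.0151) and 4.80-fold (adjusted p = 0.0155), and GSC rose 2.74-fold (adjusted p = 0.026). MXD1 rose 3.16-fold (adjusted p = 0.0155, against 0.0968 without the block). Lineage genes that rose included TWIST1 (4.18-fold), POU3F2 (3.42-fold), SOX3 (2.63-fold) and COL1A2 (3.04-fold), and the interferon-induced gene MX1 rose 2.72-fold, with adjusted p-values of 0.0155 to 0.026. KLF2, a naive pluripotency factor, rose at least 3.13-fold and IL7R at least 5.09-fold, as no control array had either well above background. SLCO4A1 fell 4.26-fold, SMIM13 4.0-fold and SASH1 2.78-fold (adjusted p = 0.0279, 0.0155 and 0.0245). Of the control arrays CDKN2B and CD36 were well above background on 1, and CER1, CPLX3 and POU3F2 on 2, and SMIM13 was so on 1 N/C-MYC-silenced array. POU5F1, SOX2 and NANOG stood at 0.61, 0.72 and 0.30, TBXT, EOMES and MIXL1 at 1.10, 0.46 and 0.66, and EZH2, CTNNB1 and AXIN2 at −0.45, 0.50 and 0.29, none past the threshold in either fit, and the other AXIN2 probe, which did not represent the gene in the test, stood at 2.33. Without the block no gene passed between N/C-MYC-silenced and control cells in limma (1720 at an unadjusted p below 0.05, smallest adjusted p 0.0968). The blocked count of 195 became 11, 28 or 193 without N/C-MYC-silenced replicate 1, 2 or 3, and 5, 8 or 3 without control replicate 1, 2 or 3, and it was 0 in limma without slide 1, which holds the dim array (1812 genes at an unadjusted p below 0.05). It became 802 with normexp background correction (735 higher, 67 lower), 124 after quantile normalization (87 and 37), 43 in the authors' value table (28 and 15) and 3 without a filter on dim probes. From the compared groups only, limma called 0 (2703 genes at an unadjusted p below 0.05). Of the genes named, CPLX3 kept its blocked call in all 6 fits that left out 1 array, CDKN2B in 5 (adjusted p = 0.079 without control replicate 3) and CD36 and SMIM13 in 3. CER1, LEFTY2, ACTG2, S100A6, TWIST1, POU3F2 and MX1 kept theirs in 2, MYCN, MXD1, COL1A2, IL7R, SLCO4A1 and SASH1 in 1, and GSC, SOX3, KLF2 and CCNE2 in 0.

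PI3Kβ-depleted and PI3Kα-depleted cells were compared directly, which needs no shared control. Primitive streak and mesendoderm genes were lower in PI3Kβ-depleted cells for 21 of 28 members (median −0.70, slide medians −0.83, −0.73 and −0.84, adjusted p = 1.15e-08, and adjusted p = 0.104 with an estimated correlation). GSC was 5.47-fold lower and passed in both fits (SE 0.329, adjusted p = 0.0274, and 0.00479 with the slide block). With the slide block 8 members fell. Among them were MIXL1 (13.4-fold, adjusted p = 0.0276), LEFTY2 (11.4-fold, adjusted p = 0.00194), LEFTY1 (10.6-fold, adjusted p = 0.02), TBXT (6.94-fold, adjusted p = 0.0277), CER1 (5.92-fold, adjusted p = 0.02) and EOMES (3.07-fold, adjusted p = 0.0295). Adjusted over the list alone, 10 fell without the block and 12 with it. MIXL1 and TBXT were well above background on 2 PI3Kβ-depleted arrays, and CER1 on 2 arrays of each group. Definitive endoderm genes lay lower in 14 of 19 cases (median −0.27, adjusted p = 0.000221) and naive pluripotency genes in 9 of 13 (median −0.38, adjusted p = 0.00827), each with adjusted p = 0.104 with an estimated correlation. Of the 19 endoderm genes only 15 are not streak genes, and this shift was not tested without the shared members. All 14 histone genes lay lower (median −0.56, adjusted p = 0.00231, and adjusted p = 0.555 with an estimated correlation), and Polycomb-bound regulators did in 35 of 51 cases (median −0.25, adjusted p = 0.0281, and adjusted p = 0.918 with an estimated correlation). Conversely, 23 of 24 p53 targets lay higher in PI3Kβ-depleted cells (median 0.59, adjusted p = 8.27e-07, and adjusted p = 0.302 with an estimated correlation). Of these the death receptor gene FAS (2.59-fold, adjusted p = 0.0386) and the stress-induced gene SESN1 (2.37-fold, adjusted p = 0.0491) were higher with the slide block. POU5F1, SOX2, NANOG, EZH2, CTNNB1 and AXIN2 differed by −0.59, 0.11, −0.04, 0.24, 0.18 and 0.22 and did not pass in either fit, and the other AXIN2 probe had the opposite sign (−1.19). The streak, endoderm, histone and p53 shifts held without any one array, and the naive shift was lost without PI3Kβ-depleted replicate 1 (adjusted p = 0.0503). The Polycomb-bound shift was lost without PI3Kα-depleted replicate 1 (0.223) or 2 (0.0714) or PI3Kβ-depleted replicate 2 (0.11) or 3 (0.399). Endothelial and blood genes shifted lower only with the slide block (9 of 12, adjusted p = 0.0413, and adjusted p = 0.265 with an estimated correlation).

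Without a block 8 genes passed between PI3Kβ-depleted and PI3Kα-depleted cells (1347 at an unadjusted p below 0.05). PIK3CA, C4orf33 (4.69-fold), CYFIP2 (3.11-fold), the peroxisomal carnitine transferase gene CROT (at least 3.67-fold) and the dynein intermediate chain gene DNAI3 (at least 2.96-fold) were higher in PI3Kβ-depleted cells, the last pair without any PI3Kα-depleted array well above background. GSC, TFF3 (4.88-fold) and LRRN2 (3.1-fold) were lower, and the adjusted p-values of all 8 lay between 0.0239 and 0.0466. Each kept its call in 0 or 1 of 6 fits that left out 1 array. With the slide block 131 genes passed, 60 higher and 71 lower, including all 8 and CGA, at least 3.47-fold higher (adjusted p = 0.0057). The count of 8 became 4, 0 or 1 without PI3Kα-depleted replicate 1, 2 or 3 and 1, 0 or 0 without PI3Kβ-depleted replicate 1, 2 or 3. The blocked count became 26, 20 or 6 and 16, 42 or 2 in the same order. It became 23 with normexp background correction (13 higher, 10 lower), 40 in the authors' value table (30 and 10), 5 without a filter on dim probes and 4 from the compared groups only. In the 6 fits that left out 1 array, GSC kept its blocked call in 5 (adjusted p = 0.0528 without PI3Kβ-depleted replicate 3), PIK3CB and LEFTY2 in 6, LEFTY1 and CER1 in 3, MIXL1 in 1 and TBXT, EOMES, FAS and SESN1 in 0. The blocked limma calls of MIXL1, TBXT and EOMES held after quantile normalization (adjusted p = 0.0401, 0.0449 and 0.0348). They were lost with normexp (0.0519, 0.0745 and 0.207) and in the authors' value table (0.113, 0.172 and 0.283).

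Of the 5 comparisons made, that of N/C-MYC-silenced with PI3Kβ-depleted cells had the most genes past the threshold in both fits, and its primitive streak genes shifted as a list. N/C-MYC-silenced and PI3Kα-depleted cells were not compared. GSC was 11.2-fold higher in N/C-MYC-silenced cells (SE 0.329, adjusted p = 0.00259, and 0.000194 with the slide block) and kept its call without any one array. CER1 (25.3-fold, adjusted p = 0.0478), MIXL1 (11-fold, adjusted p = 0.0412) and EOMES (3.90-fold, adjusted p = 0.0272) were higher as well, and TBXT (9.01-fold) passed with the slide block only (adjusted p = 0.00627 against 0.0568). In all, 23 of 28 streak genes lay higher (median 1.25, slide medians 1.72, 0.85 and 1.47, adjusted p = 6.04e-08, and adjusted p = 0.0852 with an estimated correlation). Of these 5 passed over all genes and 15 adjusted over the list alone, against 14 and 18 with the slide block. Naive pluripotency genes (12 of 13, median 0.70), definitive endoderm genes (15 of 19, median 0.87) and endothelial and blood genes (12 of 12, median 0.81) shifted higher (adjusted p = 0.000494 each), and these 3 list calls alone held with an estimated correlation in the fit without the block (adjusted p = 0.0481, 0.0484 and 0.0481). All 3 were lost with the slide block and an estimated correlation (adjusted p = 0.104, 0.226 and 0.0922). DNMT3L (8.01-fold, adjusted p = 0.039) and KLF2 (at least 5.83-fold, adjusted p = 0.0227) were examples of the naive list, and SOX17 (2.82-fold, adjusted p = 0.0402) of the endoderm list. Among WNT targets 20 of 29 lay higher (median 0.43, adjusted p = 0.0075, and adjusted p = 0.391 with an estimated correlation), with SP5 (5.65-fold, adjusted p = 0.0295) and the WNT inhibitor gene APCDD1 (6.09-fold, adjusted p = 0.0295) past the threshold. This shift was lost without PI3Kβ-depleted replicate 3 (adjusted p = 0.0946). In the 6 fits that left out 1 array, the calls of these genes other than GSC were kept in 0 to 2 without the block and in 5 or 6 with it.

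Histone genes (13 of 14, median 0.86, adjusted p = 0.00114, and adjusted p = 0.391 with an estimated correlation), Polycomb-bound regulators (39 of 51, median 0.44, adjusted p = 0.00289, and adjusted p = 0.594 with an estimated correlation), interferon response genes (15 of 19, median 0.66, adjusted p = 0.0156, and adjusted p = 0.481 with an estimated correlation) and mesoderm genes (15 of 19, median 0.86, adjusted p = 0.0415, and adjusted p = 0.761 with an estimated correlation) also lay higher in N/C-MYC-silenced than in PI3Kβ-depleted cells. Ribosome biogenesis genes (43 of 59, median −0.26, adjusted p = 0.00054, and adjusted p = 0.391 with an estimated correlation), S phase genes (22 of 30, median −0.29, adjusted p = 0.00381, and adjusted p = 0.322 with an estimated correlation), G2/M genes (26 of 31, median −0.31, adjusted p = 0.00567, and adjusted p = 0.481 with an estimated correlation) and p53 targets (17 of 24, median −0.27, adjusted p = 0.0168, and adjusted p = 0.594 with an estimated correlation) lay lower. The shift of the Polycomb-bound genes was lost without PI3Kβ-depleted replicate 3 (adjusted p = 0.0946) or N/C-MYC-silenced replicate 1 (0.157), and those of the S phase (0.06), G2/M (0.152) and histone genes (0.06) without N/C-MYC-silenced replicate 1. The p53 shift was lost without PI3Kβ-depleted replicate 1 (adjusted p = 0.126) or N/C-MYC-silenced replicate 2 (0.221). The interferon shift was lost without either of these (0.107 and 0.0838) or N/C-MYC-silenced replicate 3 (0.0544), and the mesoderm shift without PI3Kβ-depleted replicate 2 (0.133) or 3 (0.552) or N/C-MYC-silenced replicate 1 (0.39). Fibroblast markers shifted higher only with the slide block (12 of 15, adjusted p = 0.0161, and adjusted p = 0.22 with an estimated correlation).

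Other genes that rose were CALHM4 (22.7-fold), CPLX3 (9.92-fold), CD36 (at least 8.93-fold) and the defensin gene DEFB1 (at least 8.03-fold), with adjusted p-values of 0.0228 to 0.0412. Genes that fell were SMIM13 (4.94-fold), SASH1 (3.61-fold), TEX15 (3.89-fold), the neurotrophic factor gene CDNF (at least 2.55-fold) and CROT (3.22-fold), with adjusted p-values of 0.0228 to 0.0272, and SASH1 had a further probe of opposite sign. With normexp background correction CDNF and TEX15 turned to 0.38 and 0.05. TEX15 and SMIM13 were well above background on 1 and CROT on 2 N/C-MYC-silenced arrays, and CALHM4 and CPLX3 on 1, MIXL1, TBXT and CER1 on 2 PI3Kβ-depleted arrays. IGFBP5, an insulin-like growth factor binding protein gene, was 17.0-fold higher and CGA 8.35-fold lower with the slide block only (adjusted p = 2.99e-05 and 0.00232). POU5F1, SOX2, NANOG, EZH2, CTNNB1 and AXIN2 differed by 0.65, 0.11, 0.65, 0.00, 0.49 and 0.43 and did not pass in limma without the block, and the other AXIN2 probe differed by 2.72. Without a block 68 genes passed between N/C-MYC-silenced and PI3Kβ-depleted cells, 55 higher and 13 lower (2533 at an unadjusted p below 0.05), and with it 875, 632 higher and 243 lower, which included all 68. In the 6 fits that left out 1 array, the calls named here were kept in 0 to 2 without the block. The count of 68 became 14, 2 or 1 without PI3Kβ-depleted replicate 1, 2 or 3 and 9, 16 or 1 without N/C-MYC-silenced replicate 1, 2 or 3. The blocked count became 298, 304 or 186 and 367, 515 or 611 in the same order. It became 227 in the authors' value table (134 higher, 93 lower), 324 without a filter on dim probes (272 and 52) and 85 from the compared groups only. It was 709 after quantile normalization (418 and 291) and 940 with normexp background correction (803 and 137).

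**Figure D3:**
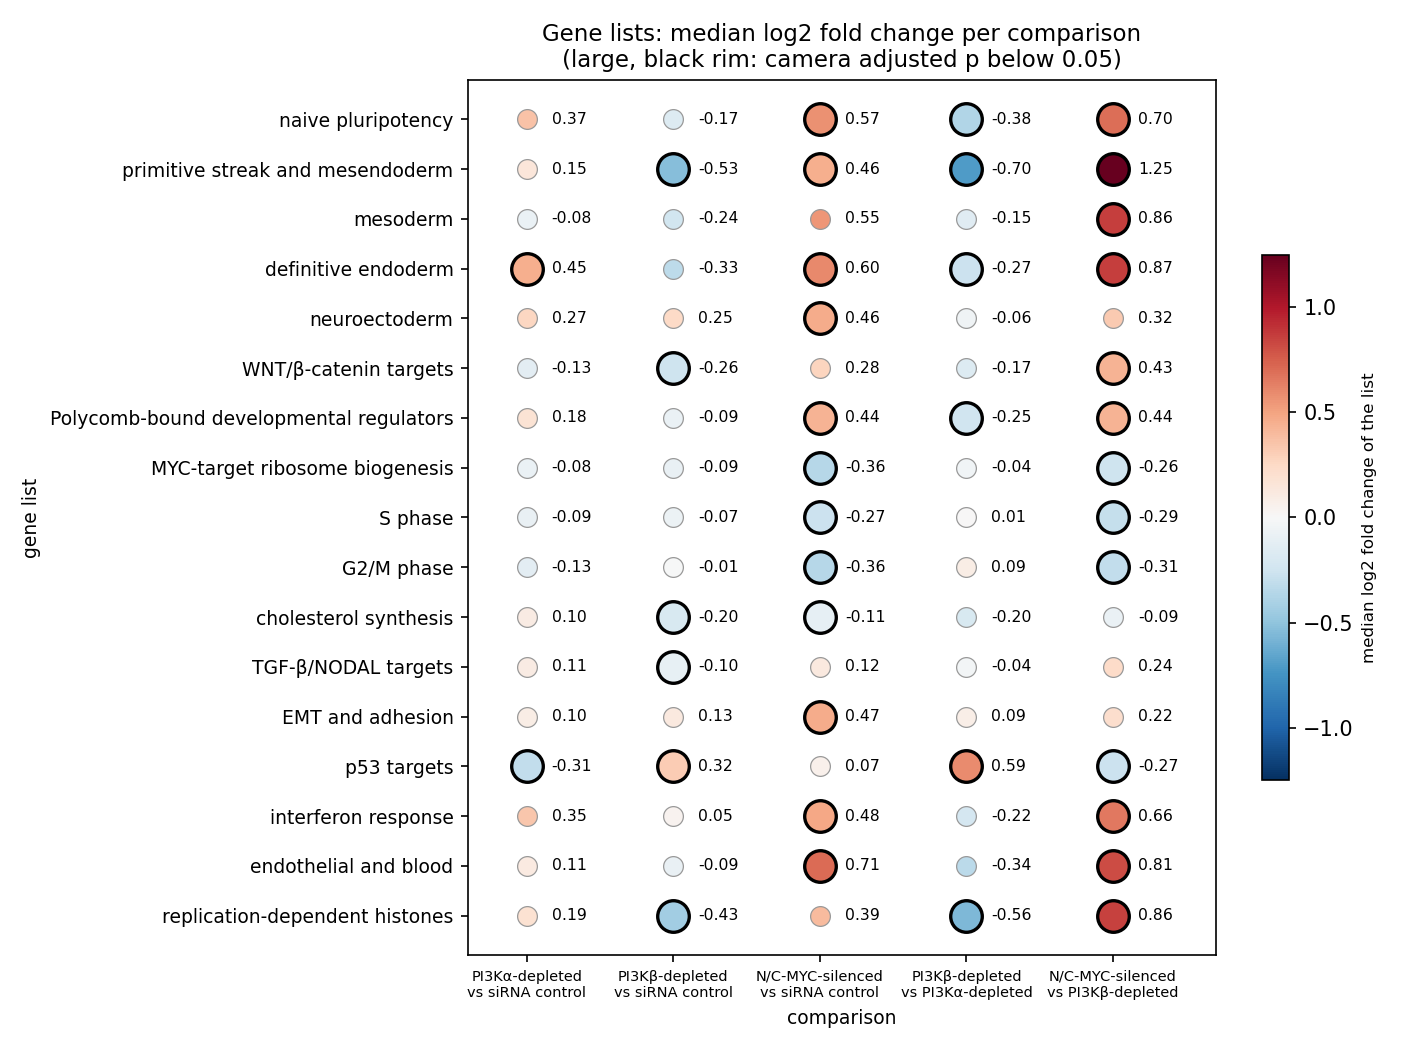
Median log2 fold change (colour and printed value) of the 17 gene lists (y axis) that had a camera adjusted p below 0.05 in at least 1 of the 5 comparisons (x axis), with large black-rimmed circles where it did. Primitive streak genes have a median of −0.53 in PI3Kβ-depleted and 0.46 in N/C-MYC-silenced cells against control.

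The remaining 18 lists had no adjusted p below 0.05 in any comparison without the block: core pluripotency, PI3K subunits, the MYC network, neural crest, trophoblast and amnion, WNT pathway components, PRC2 and PRC1 subunits, HOX clusters, cytosolic ribosomal proteins, FOXO targets, glycolysis, hypoxia response, the stress response targets of ATF4, immediate early genes, RNAi machinery, fibroblast, neurons and glia, and reference genes. For PI3Kβ-depleted against control cells, core pluripotency genes had a median of −0.08 over 40 members (adjusted p = 0.402) and PRC2 and PRC1 subunits, to which EZH2 belongs, of −0.03 over 29 (adjusted p = 0.903). The median, the mean and the direction of the test differed in sign in 33 of the 175 list tests, none of them among the 39 with an adjusted p below 0.05.

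The 3 comparisons with control share the control arrays, so their fold changes correlate without any effect. Across 14527 genes, which are not independent replicates, Pearson's r was 0.278 between the PI3Kα and PI3Kβ comparisons (0.501 in simulated unchanged groups against the same controls), 0.355 between PI3Kα and N/C-MYC (simulated 0.5) and 0.119 between PI3Kβ and N/C-MYC (simulated 0.5). The covariances were 0.0471, 0.0813 and 0.0259 against simulated values of 0.0512, 0.0510 and 0.0511, which leaves differences of −0.00409, 0.0302 and −0.0252. Without the block no gene passed in more than 1 of these comparisons. With it GSC (lower in PI3Kβ-depleted, higher in N/C-MYC-silenced cells) and LOC100131820 (higher in both) did so. At most 1 gene did in 100 simulations of unchanged groups, which give few calls in any comparison and so are no yardstick. Independent lists would give 0.02 in each of these directions, a value that leaves out the shared controls. The 3 control arrays are too few to split, and part of any overlap may come from them. Between the direct comparisons, which share the PI3Kβ-depleted arrays, r was −0.539 (simulated −0.500) and the covariance −0.170 (simulated −0.0510, a difference of −0.119). With the slide block 66 genes passed in both, of which 54 were lower in PI3Kβ-depleted than in PI3Kα-depleted cells and higher in N/C-MYC-silenced than in PI3Kβ-depleted cells, and 10 the reverse. In 100 simulations of unchanged groups that share these arrays, 0 genes passed in both. Unchanged groups give few calls in any comparison, so this 0 is no yardstick for the 66 genes or their directions. Independent lists would give 2.91 and 0.95, values that leave out the shared arrays, which favour opposite directions, and part of the overlap may come from them.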

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

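Of the tests in this part, those of primitive streak genes against other differentiation genes, pooled or list by list, and the shares of higher genes at an unadjusted p after other scalings were chosen after the result was seen. Probes without a gene name, which enter no comparison above, were also tested: of 1530 such probes, 2 were higher in N/C-MYC-silenced than in control arrays with the slide block and 1 passed without it. Between N/C-MYC-silenced and PI3Kβ-depleted arrays 4 were higher with the block and 2 passed without it.

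Primitive streak genes were lower in PI3Kβ-depleted than in control arrays. If dim probes near background were the cause, the 19 members well above background on all 12 arrays would not be lower on every slide, but their mean differences were −0.50, −0.38 and −0.84, the highest being −0.377, which argues against dim probes as the only cause. Over all 28 members the means were −0.77, −0.526 and −1.18. The dimmer members thus lay lower still and hold part of the difference. If fewer differentiated cells of every kind were the cause, every other differentiation list would be as low, but the 28 streak genes differed from 64 genes of the mesoderm, neuroectoderm, neural crest and trophoblast lists by −0.95, −0.60 and −1.20, the highest being −0.604, and without streak genes the trophoblast list averaged 0.36, 0.43 and 0.13 and the neuroectoderm list 0.16, 0.07 and 0.32, which argues against every kind, though neurons and glia genes were lower (−0.208, −0.314 and −0.065, with the streak genes differing from them by −0.212 on slide 2) and neural crest genes mixed (0.033, −0.143 and −0.206). Fewer cells of the streak and of mesoderm, endoderm and endothelium stay open, with these lists taken without streak genes. The endothelial and blood list averaged −0.346, −0.036 and −0.388, with 7 of 12 genes lower. The mesoderm list averaged 0.257, −0.071 and −0.326, with 13 of 17 genes lower. The definitive endoderm list, with 8 of 15 genes lower, did not fall on average (0.019, −0.007 and 0.003). The medium is not given per sample and stays open, and the position on the slide, which is the same for a group on every slide, cannot be told apart from PI3Kβ depletion, so that lower expression of streak genes after it remains a hypothesis, whose list call was lost with an estimated correlation (adjusted p = 0.265).

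More genes were higher than lower in N/C-MYC-silenced than in control arrays, 65.9% of the 2988 genes at an unadjusted p below 0.05 with the slide block. The dim replicate 1 array as the cause is argued against by 67.8% of 1812 genes without slide 1 (66% to 67.8% without any one slide). Scaling on the 75th percentile stays open, since quantile normalization, which can also remove a true shift of this kind, left 50.2% of 2749 genes higher (49.4% to 54.1% without any one slide), centring on the median 56.8%, the values deposited by the authors 51.5% and normexp 83.6%. Among genes called with the block the share went from 83.1% to 70.2% after quantile normalization, which meets the bound of 60% set against this explanation, but that bound was wrong because it covered 124 called genes and not those of the pattern. Dim probes near background stay open too, as do, untested, a biological effect of N/C-MYC silencing and the position on the slide. Of the 2296 genes well above background on all 12 arrays, 62% were higher (61.4% to 64.6% without any one slide). This meets the same bound, but the filter kept most of the genes, and above the median mean level the share was 50.8% of 1215.

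Other splits of the arrays were too few for a share under 0.05. Of the 10 splits of the 6 arrays in each comparison, all 10 gave as many genes as the real one in the comparisons with control of PI3Kα, PI3Kβ and N/C-MYC (real count 0 in limma, with 841, 631 and 1720 genes at an unadjusted p below 0.05, highest other 0), and 1 did, the real one, between PI3Kβ and PI3Kα depletion (8, highest other 0) and between N/C-MYC silencing and PI3Kβ depletion (68, highest other 0). With the slide block, of the 4 splits that part all slide pairs, 4 gave as many in the PI3Kα comparison (0) and 1 in each of the others (4, 195, 131 and 875, highest other 0).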

How the results depend on the processing

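The fits without slide 1 or the dim array, those combining an alternative with the slide block, and the blocked list test with an estimated correlation were chosen after the data were seen. Counts of genes moved by over 1.5 times as follows, and the cause was not tested. PI3Kα against control (0 genes) gave 1 after quantile normalization and 0 to 1 leaving out 1 array. PI3Kβ against control (0) gave 4 with the slide block and 2 with it without slide 1. N/C-MYC against control (0) gave 1 with normexp, 213 with array weights, 195 with the slide block and 11 with it without the dim array. PI3Kβ against PI3Kα (8) gave 3 with normexp, 0 without a filter on dim probes, 1 from the compared groups only, 131 with the slide block, 17 with it without slide 1, and 0 to 4 leaving out 1 array. N/C-MYC against PI3Kβ (68, 55 higher and 13 lower) gave 38 after quantile normalization (26 and 12), 7 with normexp, 4 in the authors' table (2 and 2), 1 without a filter, 339 with array weights and 0 from the compared groups only. It gave 875 with the slide block, 126 with it without slide 1, 367 with it without the dim array, and 1 to 16 leaving out 1 array. Of the 39 list calls 3 held with an estimated correlation and 0 with it and the slide block, and genes called in more than 1 comparison with control went from 0 to 2 with the block. CDNF, CASC2 and TEX15, lower in N/C-MYC-silenced than in PI3Kβ-depleted cells, turned to 0.38, 0.53 and 0.048 with normexp, and CASC2 to 0.57 without a filter. Blocked splits of higher against lower calls moved for N/C-MYC against control from 83.1% higher to 70.2% after quantile normalization, 65.1% in the authors' table and 91.6% with normexp. For N/C-MYC against PI3Kβ they moved from 72.2% to 59% in both and to 85.4% with normexp, and for PI3Kβ against PI3Kα from 45.8% to 75% in the authors' table and 56.5% with normexp. The median of all genes moved with normexp to 0.27 in N/C-MYC against control (0.07 before) and to 0.26 against PI3Kβ (0.04 before). Of the named genes' results, leaving out 1 array left the call or its absence as it was in 1269 fits and ended a call in 180. The 1269 pool results that were never called with calls that were kept, so they do not measure how well calls held. Calls made without the block were mostly lost in these fits, as given gene by gene above. The slide block brought 134 of them past the threshold and changed no other call of a named gene, and it added 5 list calls. Genes were also named because the blocked fit called them. The 134 therefore follow in part from that choice and do not measure the effect of the block. Signal over background limits PI3Kα-depleted replicate 1 most (58.1% of spots well above background), followed by N/C-MYC-silenced replicate 1 (63.2%), the array with the lowest 75th percentile.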

Other observations

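The combined test of the 3 silenced groups against control was chosen after the result was seen. No comparison above tests for genes that differ from control whichever gene was silenced, although MXD1 and LOC100131820 passed in single comparisons with the slide block. MXD1, the MAX partner that opposes MYC, was higher by 1.56 on the log2 scale in the 3 silenced groups together, on all 3 slides (adjusted p = 0.0626 in limma, and 0.0529 with the slide block), and did not pass. LOC100131820 stood 1.79 higher, on all 3 slides, and did not pass either (limma adjusted p = 0.0915 with the slide block). No control array had its probe well above background, and its bound for PI3Kβ depletion against control was at least 1.48-fold. MEF2C, which encodes a muscle and neuronal transcription factor, stood 1.54 higher and ZNF215 1.37 higher, and PVALB, which encodes the calcium buffer parvalbumin, at −1.11, with adjusted p-values of 0.276 to 0.371 with the slide block. In all, 17 of 14527 genes were at least 2-fold from control in the same direction in all 3 silenced groups, 15 higher and 2 lower. These folds are fitted values, without the bound used for dim probes. Chance in the shared control arrays gave a mean of 7.59 (SD 2.76) and at most 15 in 100 simulations of unchanged groups. The margin of 17 over 15 is smaller than that SD and the control lay at one position on every slide, so chance, position and a response common to silencing cannot be told apart. No gene passed in the combined limma test, with 1220 genes at an unadjusted p below 0.05 with the slide block and 576 without it. The latter number is below the share that chance alone would give, and the former is above it.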
